A study of Mus musculus with 4 samples.

How the data were processed

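RNA was measured in 4 samples, 1 array per group: cultured adipocytes with vehicle, cultured adipocytes with forskolin, epididymal fat on chow and epididymal fat on the high fat diet. Per the labels, total RNA was extracted with a phenol reagent, cleaned on a column, labelled with biotin and handled by Affymetrix protocols. Each value is an expression index per probe set, an intensity on a linear scale, as deposited by the authors. The software, background correction and normalization behind it are not given in the sources used here. The array medians differed, so the deposited intensity values were not quantile normalized across the 4 arrays. The second table repeats the same intensities, equal in 90504 of 90504 cells. It adds, per the file headers, the authors' fold changes with a lower and an upper bound, whose confidence level is not given in the sources used here. Those folds lay within 1% of the ratio of the intensities for 22272 of 22277 probe sets in the forskolin comparison and 22061 of 22061 in the diet comparison.

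Empty cells were left out (99, 74, 271 and 176 on the vehicle, forskolin, chow and high fat arrays). Some cells were 0 (36, 38, 24 and 19), so each array was floored at its 10th percentile (22.1, 22.23, 25.08 and 26.03) before taking log2. A fold against an array at its floor is a lower bound, given as "at least". Probe sets were named by the gene ID in the deposited table through a RefSeq gene table of assembly GRCm38.p6, used for names only. The gene ID matched for 20834 probe sets, a symbol for 42 and a synonym for 183; for 316 the table's own symbol was kept. No gene was named for 769 probe sets, and 482 with several genes were not used for genes. Probe sets ending in _s_at (1469) or _x_at (1512) can read several transcripts.

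A gene was its probe set with the highest mean log2 level over the arrays among those with the most values, which gave 13108 genes. The genes with several probe sets numbered 5159. Among compared genes with 2 or more probe sets, the median gap between them was 0.126 on the log2 scale for forskolin (2158 genes) and 0.395 for diet (1591 genes). The log2 levels correlated across probe sets with Pearson's r of 0.986 between the adipocyte arrays and 0.911 between the fat arrays. The difference was the log2 level with forskolin minus vehicle, or high fat diet minus chow. Genes counted had to reach the median level of all genes on the brighter array of the pair and a fold of 2. Counts within gene lists were taken over all measured members, whatever their level. No p-value was computed, because each group held 1 array.

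The 28 gene lists, 17 of pathways or housekeeping genes and 11 of cell markers, were written before the data were examined, as were the rule for naming genes and the main settings. Each list's median was placed among 10000 random lists of the same size, drawn from genes in the same of 20 level bins. The named genes per comparison were the 12 with the largest and the 12 with the lowest difference that passed the level filter, leaving out clone, predicted and EST names, and a fixed set of cAMP, adipocyte, inflammation and lipid genes whatever their value. In each list described, the 2 to 4 members with the largest absolute difference passing the filter were named, and genes 2-fold apart in both comparisons were named for that, after their values were seen. Endothelial and cell cycle markers that went against their list's median were also named after their values were seen, as were the neutrophil genes S100a8 and S100a9. Some genes that these rules select are not reported here. Shares by CRE class were set against random genes matched on level. Intervals over genes in the closing section come from 10000 bootstrap draws.

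The alternatives were a fold threshold of 1.5 or 3, no level filter or the 75th percentile, centring or quantile normalization, 16 added before log2, the median or all of a gene's probe sets, and the authors' folds. Centring on the compared genes and the authors' bounds were added after the data were seen. In the authors' deposited table, the bound nearer to no change lay above 1 for 82 of the 82 higher and 8 of the 9 lower forskolin genes, and for all 1119 and 429 diet genes. With 1 array per group, these bounds cannot hold the variation between cultures or mice, so they do not show that the calls would repeat.

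The steps were tested on simulated arrays made from the mean levels of each pair, with the central spread of the real differences as noise and 100 genes changed by each of 2 folds. For forskolin (6670 genes), 100% of the genes changed 3-fold and 100% of those changed 8-fold were found, with 0 unchanged genes called. This noise leaves out the tails of the differences and any variation between cultures, so the 0 calls give no rate of false calls. For the diet (7149 genes), 74% and 100% were found, with 683 unchanged genes called higher and 657 lower. Of 200 unshifted lists of 15 genes, 5% fell outside the central 95% for forskolin and 6.5% for the diet. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.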

Results

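RNA from mouse fat was measured on 4 Affymetrix arrays of 22626 probe sets, each a group of probes that reads the transcript of a gene. In the cell experiment, primary adipocyte cultures made from visceral fat received DMSO vehicle or 10 µM forskolin, a plant compound that activates adenylyl cyclase and so raises cAMP, and RNA was taken after 2 h. In the diet experiment, whole epididymal fat pads came from chow-fed control mice or from mice given a 60% high fat diet over 12 weeks. Each of the 4 groups held 1 array, so the differences have no replicate check, no test was run, and the number of arrays limits the precision. The median intensity per array was 236.5 with vehicle, 237.3 with forskolin, 265.7 on chow and 314.4 on the high fat diet.

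The forskolin comparison asked which adipocyte genes respond to raised cAMP. Forskolin-treated adipocytes had higher levels of early cAMP-responsive genes. Few of the compared genes differed 2-fold from vehicle, and most that did were outside the list of early cAMP targets described below. Of 6704 genes at or above the level filter, 82 were at least 2-fold higher and 9 at least 2-fold lower, while 97.0% lay within 1.5-fold. Fos, a transcription factor of the AP-1 family, was 11.7-fold higher (intensity 331.2 with vehicle and 3884 with forskolin). Nr4a1, an orphan nuclear receptor, was 11.1-fold higher, and Irs2, which relays the insulin signal, was 9.98-fold higher. The highest fold difference was that of the homeobox gene Hoxa5, at 19.5-fold. In the authors' deposited table, the bounds of the fold for Fos were 9.71 and 14.7, which with 1 array per group cannot hold variation between cultures.

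Of the 20 measured members of the list of early cAMP and CREB targets, 17 were at or above the level filter. Over all 20, 15 were at least 2-fold higher with forskolin, Pde4b among them, and none was 1.5-fold lower. The list's median was 3.84-fold higher, at percentile 100 among 10000 level-matched random lists, which is a description of these libraries. Rgs2, a regulator of G protein signalling, was 9.68-fold higher and Crem, a CREB family member, 6.52-fold higher. Nr4a2 was 4.05-fold higher, the clock gene Per1 3.64-fold and Atf3 3.25-fold. Sik1, a kinase that restrains CREB signalling, was 1.85-fold higher, and Nr4a3 1.26-fold. Ppargc1a, a coactivator of mitochondrial genes, was 1.82-fold higher and Pde4b, a phosphodiesterase that degrades cAMP, 2.12-fold higher, both at levels below the filter. Pde4d was not analysed here.

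The other genes highest with forskolin were Nap1l5 (18.3-fold), the Ras-related gene Rasd1 (16.7-fold), Ddit4, an inhibitor of mTORC1 (13.0-fold), the potassium channel subunit Kcne4 (8.81-fold), Zfp707 (8.51-fold), the hyaluronan-binding Tnfaip6 (7.60-fold) and the protease Adamts4 (7.16-fold). The lowest were Ins2 (3.47-fold lower), Txnip, which inhibits thioredoxin (2.48-fold), Cmtm3 (2.40-fold), Sv2a (2.34-fold), the interferon regulatory factor Irf1 (2.20-fold) and Fam13b (2.20-fold). Ptpn6 was 2.11-fold lower, Egln3 2.10-fold, Rcan3 2.01-fold, Top3b 1.98-fold, Rhbdl3 1.88-fold and Fastk 1.87-fold. The probe sets of Ins2, Ptpn6, Top3b and Fam13b carry suffixes that mark probes shared between transcripts. In the authors' deposited table, the bounds of the fold for Ptpn6 were 0.64 and 5.22, on both sides of 1. The signs of Egln3 and Rcan3 turned when the median over a gene's probe sets was taken, to a log2 difference of 0.67 and 0.06. Rgs2 moved from 3.28 to 4.78 on the log2 scale under that choice, Top3b to -0.31 and Rhbdl3 to -0.16.

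Most genes of the fat cell lists lay within 1.5-fold with forskolin. The hormone genes Adipoq and Retn were 1.02-fold higher and 1.02-fold lower, at vehicle intensities of 10260 and 10720 near the highest value on that array, 13690, and the glucose transporter gene Slc2a4 was 1.03-fold higher at a level below the filter. Of the 16 adipocyte identity and insulin response genes, 15 lay within 1.5-fold after flooring, the exception being Irs2. Pck1 was counted within 1.5-fold only as a lower bound. It was at least 1.23-fold lower by 1 of 2 probe sets, with forskolin at the floor, and 2.94-fold lower in the authors' deposited table. In the lipid droplet list 9 of 12 lay within 1.5-fold and none was lower than that. In the lipogenesis list 15 of 16 lay within 1.5-fold, and Dgat1, which makes triglyceride, was 6.64-fold higher. All 22 oxidative phosphorylation genes (median 0.03, and -0.03 after quantile normalization), all 17 fatty acid oxidation genes and all 20 matrix genes lay within 1.5-fold. In the clock list Nfil3 was 5.11-fold higher and Bhlhe40 2.14-fold higher, and in the hypoxia list Vegfa, an angiogenic growth factor, was 3.87-fold higher. In the inflammatory list Ptgs2 was 2.28-fold higher and Il6 1.87-fold. Ucp1, the uncoupling protein of brown fat, was at least 13.6-fold higher, with vehicle at the floor and forskolin at 300.2, below the level filter.

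Of the 28 lists, 22 had a forskolin median inside the central 95% of random lists. Besides the cAMP list, the lipogenesis list (median log2 difference 0.10), the macrophage list (0.11, with 6 of 22 members at or above the level filter) and the endoplasmic reticulum stress list (0.10) lay just above it. The T cell and the neutrophil and mast cell lists lay below it (-0.48 and -0.29) with 0 and 1 members at or above the level filter.

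The authors' deposited table gives each gene a class for a predicted CRE, the site that CREB binds, with or without a TATA box. Of 659 genes classed CRE_TATA, 32 were at least 2-fold higher with forskolin (4.86%), against a mean of 7.4 and a central range of 3 to 13 among level-matched random genes. The class CRE_NoTATA held 19 such genes of 1188 (1.60%; random range 8 to 23) and the class others 22 of 4203 (0.52%; random range 38 to 65). Fos, Nr4a1, Rgs2, Per1 and Atf3 were classed CRE_TATA, whereas Crem was classed others. With the high fat diet, 104 of 689 CRE_TATA genes were at least 2-fold higher (15.1%; random range 89 to 126), 120 of 1206 CRE_NoTATA genes (9.95%; 164 to 212) and 815 of 4568 others (17.8%; 697 to 791). How the classes were made is not given in the sources used here, and the use of them was decided after the data were seen.

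**Figure D1:**
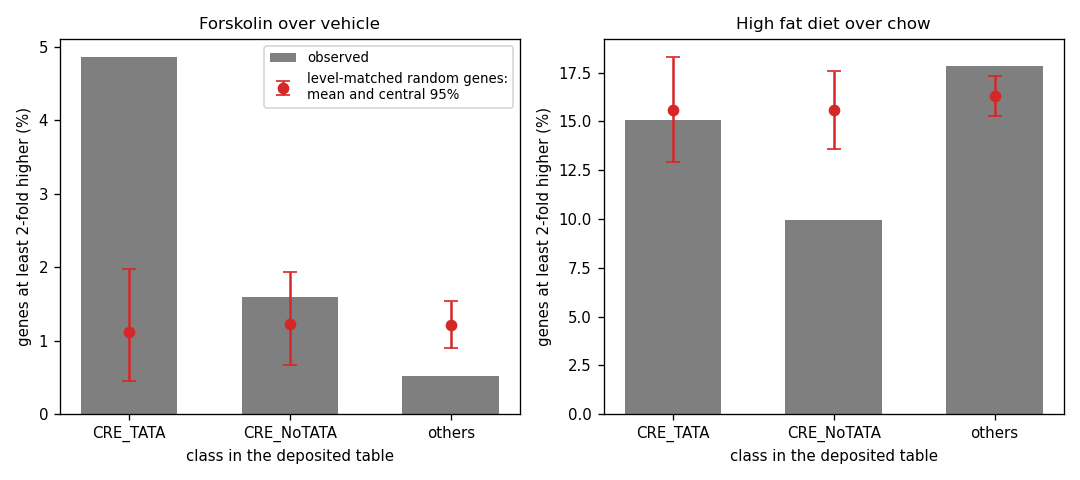
Bars show the percent of genes at least 2-fold higher by the class in the authors' deposited table, for forskolin over vehicle (left) and the high fat diet over chow (right), with 1 array per group. Red points and whiskers give the mean and central 95% of level-matched random genes; with forskolin the CRE_TATA bar stands at 4.86%.

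The diet comparison asked how fat tissue differs after long high fat feeding. At their medians, the lists of macrophage, lymphocyte, mast cell, cell division and cholesterol synthesis genes were higher on the high fat diet. The lists of branched-chain amino acid breakdown genes and of mesothelial and smooth muscle markers were lower at their medians. Of 7183 genes, 1119 were at least 2-fold higher and 429 at least 2-fold lower, and 57.7% lay within 1.5-fold. Trem2, a receptor of lipid-associated macrophages, was 132-fold higher by 1 probe set (3534 on the high fat diet and 26.82 on chow, near that array's floor of 25.08). Its log2 difference was 7.04, and 4.07 with the median over its probe sets. Lep, the gene of the satiety hormone leptin, was 6.83-fold higher (808.3 and 5517), while Adipoq was 1.05-fold lower.

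The split of higher and lower genes depended on the scaling between arrays. Higher genes were 72.3% of the calls as deposited, 50.8% after quantile normalization (874 higher and 845 lower), 59.5% after centring on the median of the compared genes (910 and 619) and 68.2% after centring on the median of all genes. The median difference of the compared genes was 0.17 on the log2 scale as deposited and -0.10 after quantile normalization. That of all genes was 0.05 and -0.10. List medians are therefore set against level-matched random lists, which share that shift. When the central spread of the observed differences was treated as noise in simulated arrays, 683 unchanged genes passed 2-fold upward and 657 downward. That spread includes any real differences.

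Of 23 listed macrophage markers, 18 were measured in the diet comparison, against 22 in the forskolin comparison. All 18 were at least 1.5-fold higher on the high fat diet and 16 at least 2-fold, with a median of 6.55-fold (percentile 100). The elastase gene Mmp12 was 66.3-fold higher, the integrin gene Itgax 31.5-fold, Gpnmb 18.5-fold, the lysosomal gene Cd68 10.4-fold and Adgre1, a macrophage surface receptor gene, 6.64-fold. Of 20 chemokine and cytokine genes, 14 of them at or above the level filter, 9 were at least 2-fold higher and 1 lower. Ccl5 was 17.6-fold higher, Ccl8 10.1-fold and Ccl2, which attracts monocytes, 5.79-fold, while Ptgs2 was 2.13-fold lower by its main probe set and higher by its other. The T cell list, with 6 of 9 listed members measured, was 3.60-fold higher at its median, and 3 of the 6 were at or above the level filter. Over all 6, 4 were at least 2-fold higher and 1 lower, with Il7r 29.8-fold and Lck 5.94-fold higher. The B cell list was 3.10-fold higher, with 2 of 7 members at or above the level filter. Over all 7, 5 were at least 2-fold higher, among them the immunoglobulin gene Ighm (12.3-fold) and Cd22 (7.03-fold). In the neutrophil and mast cell list (median 5.34-fold higher), the mast cell protease genes Mcpt4 and Tpsb2 were 30.2-fold and 7.54-fold higher. Its neutrophil genes S100a8 and S100a9 were 2.35-fold and 1.3-fold higher, so the median reflects the mast cell genes. Each of these lists lay above the central 95% of random lists.

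Among the other genes with the highest folds, Rgs1 was at least 115-fold higher, with chow at the floor. Glipr1 was 53.7-fold higher, Hal, which degrades histidine, 43.6-fold, Csprs at least 40.6-fold, the adaptor gene Lat2 37.3-fold, the complement receptor gene C5ar1 34.8-fold, Slc15a3 34.6-fold, the osteopontin gene Spp1 at least 34.1-fold and Adam8 33.1-fold. Csprs moved to a log2 difference of 3.71 with the median over probe sets. The probe set of Trem2 can also read other transcripts, by its suffix.

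Of 14 measured cell cycle genes 9 were at least 2-fold higher, with a median of 5.62-fold, including Birc5 (10.9-fold), Ccnb2 (10.1-fold) and Mki67 (7.46-fold). Top2a was 10.6-fold higher by 1 of 2 probe sets. Another 3 members were at least 1.5-fold lower, namely Cdc20 (1.85-fold, by 1 of 3 probe sets), Ccna2 (1.58-fold, by 1 of 2) and Tyms (1.67-fold, below the level filter). Cholesterol synthesis genes were 1.71-fold higher at the median, with 7 of 14 at least 2-fold higher, 5 within 1.5-fold and 2 at least 2-fold lower. Fdps was 4.50-fold higher, Dhcr7 3.68-fold and Msmo1 3.60-fold. Of 8 fat expansion markers 4 were at least 2-fold higher, namely Sfrp5 (8.04-fold), Lep, Npr3 (5.23-fold) and Mest (3.06-fold). Matrix genes were 1.51-fold higher at the median, with Tgfb1 9.02-fold, Timp1 7.20-fold and Timp2 2.73-fold higher and Ccn2 2.64-fold lower.

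Branched-chain amino acid breakdown genes were 1.69-fold lower at the median (percentile 0), with 5 of 15 at least 2-fold lower and none 2-fold higher. Hibch, of the valine pathway, was 4.20-fold lower, and Dbt, Bckdhb and Bckdha, subunits of the branched-chain ketoacid dehydrogenase, were 2.99-fold, 2.73-fold and 2.02-fold lower. The adipocyte list lay inside the random range, with a median log2 difference of -0.03. Within it Irs1 was 3.90-fold lower, the resistin gene Retn 3.48-fold and Cfd 2.13-fold, while Slc2a4 was 1.42-fold higher at a level below the filter. The lipid droplet list lay below the random range (median -0.22), with Abhd5 2.33-fold lower and Plin2, a lipid droplet coat protein gene, 1.76-fold higher. In the lipogenesis list (median -0.15, inside the range) Gpam was 3.94-fold lower, Dgat1 2.49-fold lower and Scd2 3.15-fold higher, whereas Scd1 and Fasn were 1.01-fold and 1.19-fold lower. Acaca was 2.31-fold lower and Ppargc1a 2.62-fold lower, both below the level filter. Adipoq, Retn, Scd1 and Cfd had intensities of 10460, 10060, 11270 and 12080 on chow, near the highest value on that array, 13700. Fabp4 and Lpl, also in the adipocyte list, had 12620 and 10680. The adipocyte and lipid droplet genes at or above the level filter had a joint median log2 difference of -0.25. For those with chow intensities under 5000 it was -0.64, so the adipocyte median near 0 depends on the brightest genes counted.

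Oxidative phosphorylation genes (median -0.05; 21 of 22 within 1.5-fold) and fatty acid oxidation genes (median -0.15; 12 of 16 within 1.5-fold) lay below their random ranges, with Cpt1a, which admits fatty acids to mitochondria, 4.19-fold higher and Eci1 1.73-fold lower. The hypoxia list was 1.45-fold lower at the median, with Vegfa 5.29-fold, Egln3 2.89-fold and Hk2 2.16-fold lower. The clock list was 1.44-fold lower, with Per3 2.46-fold and Cry2 2.00-fold lower. Among tissue markers, the mesothelial list was 2.74-fold lower, with Msln 2.47-fold, Upk3b 1.97-fold and Wt1 1.86-fold lower. The smooth muscle and pericyte list was 2.05-fold lower, with Rgs5 1.87-fold lower and Myh11 2.59-fold lower by 1 of 2 probe sets. The endothelial list was 1.60-fold lower at its median, with 6 of 10 members at least 1.5-fold lower and 0 at least 2-fold. Emcn and Kdr were 1.82-fold and 1.81-fold lower, while the other 4 members, Tie1, Pecam1, Cldn5 and Egfl7, were 1.27-fold, 1.25-fold, 1.20-fold and 1.08-fold higher. These marker lists lay below the random range, and the fibroblast list (1.37-fold higher; Thy1 2.91-fold and Lum 2.44-fold higher) inside it. The lists of cAMP targets, thermogenic genes, endoplasmic reticulum stress, housekeeping genes, skeletal muscle, epididymis and red blood cells lay inside it too. The cAMP and stress medians were 0.05 and 0.15 as deposited and -0.17 and -0.15 after quantile normalization.

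Among the named genes lowest on the high fat diet was Acsm3, which encodes a medium-chain acyl-CoA synthetase, at 25.6-fold lower. The cytochrome P450 gene Cyp2b10 had a log2 difference of -3.81. Serpina3k was 9.64-fold lower, the albumin gene Alb 9.30-fold, Eci3, an enzyme of fatty acid oxidation, 7.80-fold and the glutathione transferase gene Gsta4 6.98-fold. Cntn2 was at least 20.9-fold lower, with the high fat array at its floor, and 68.1-fold lower in the authors' deposited table. Sema3b was 12.3-fold lower, Actl7b 9.56-fold, St6galnac5 8.15-fold, Slc44a3 6.89-fold and Clmn 6.73-fold. With the median over probe sets, Sema3b had a log2 difference of 0.05, so its direction rested on 1 of 3 probe sets, Serpina3k and Clmn were -1.84 each, and Cyp2b10 was -4.73.

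**Figure D2:**
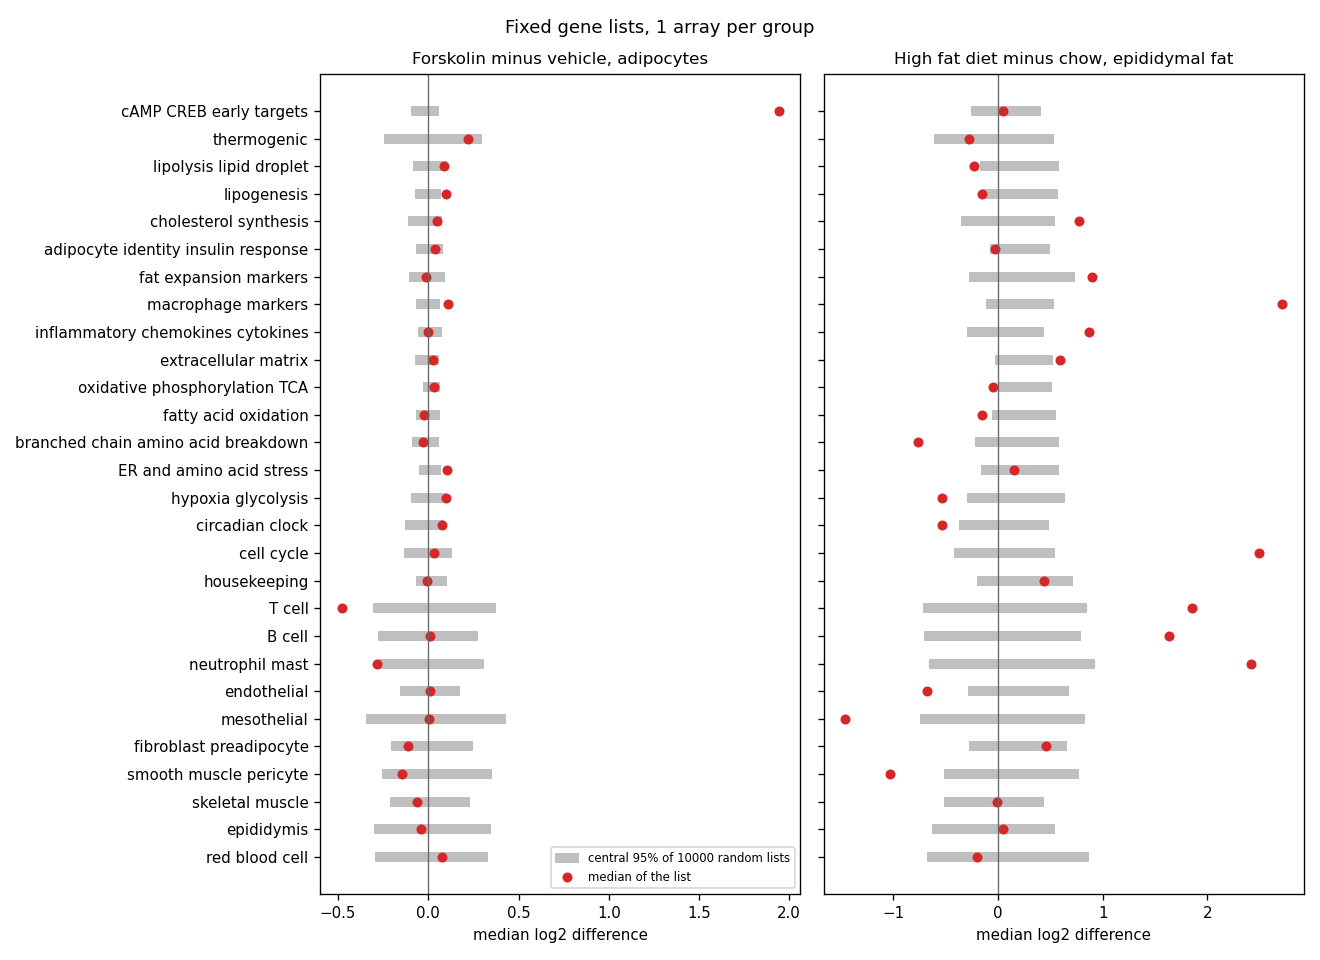
Red points give the median log2 difference of each fixed gene list for forskolin minus vehicle (left) and high fat diet minus chow (right), with 1 array per group and a different horizontal scale in each panel; grey bars are the central 95% of 10000 level-matched random lists. The cAMP list stands apart with forskolin at 1.94, and the macrophage list stands highest with the high fat diet at 2.71.

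The study sets a cAMP stimulus beside obesity, so the 2 comparisons were laid over each other. Genes higher with forskolin were found among both the higher and the lower genes of the high fat diet. Of the 6053 genes passing the level filter in both comparisons, 10 were at least 2-fold higher in both, against 7.1 for independent lists. They were Atf3, Fos, Egr1, Egr2, Jun, Junb, Ccrl2, Fem1b, Gla and Hilpda. Atf3 was 20.9-fold, Egr2 19.5-fold and Fos 11.8-fold higher on the high fat diet. A set of 14 genes was higher with forskolin and lower on the high fat diet, against 2.3, among them Hoxa5 (3.25-fold lower), Kcne4 (3.88-fold), Dgat1 and Vegfa. Another 4 genes, Txnip, Irf1, Ptpn6 and Cmtm3, were lower with forskolin and higher on the high fat diet, against 1.0, with Txnip 9.95-fold higher on the diet. Egln3 alone was lower in both, each time by the probe set with the highest level, and 2 of its 3 probe sets were higher with forskolin.

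The cAMP genes Nr4a1 and Crem were 1.16-fold and 1.33-fold higher on the high fat diet, but 2 of the 3 probe sets of Crem were lower and the log2 difference of Nr4a1 was -0.005 after quantile normalization. In the authors' deposited table, the bounds of the fold for Nr4a1 were 0.47 and 3.26. All 82 forskolin-higher genes together had a median log2 difference of -0.004 on the high fat diet, inside the random range of -0.10 to 0.26 (percentile 18.2), with 14 at least 2-fold higher and 15 lower. The 59 of them that passed the level filter in both comparisons had a median of -0.13, below their random range (percentile 0.6). The 9 forskolin-lower genes had a median of 0.69 on the high fat diet, inside their random range (percentile 96.3). With forskolin, 427 genes at least 2-fold lower on the high fat diet had a median of 0.04 (percentile 100), with 20 at least 2-fold higher and 1 lower. The 1119 genes higher on the high fat diet had a median of -0.02 with forskolin (percentile 0.6), with 16 at least 2-fold higher and 8 lower. These summaries and the counts of opposite directions were chosen after the data were seen. Across the 6053 genes, which are not replicates, Pearson's r between the differences was -0.09 and Spearman's rho -0.11. The comparisons shared no array.

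**Figure D3:**
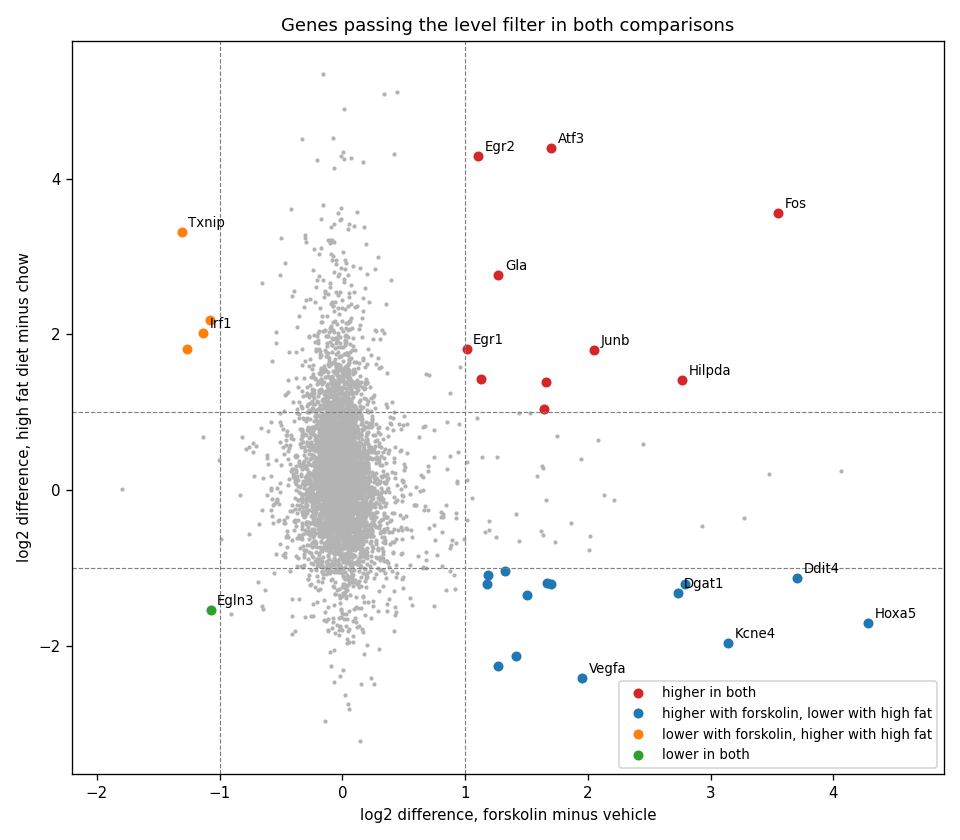
Each point is a gene passing the level filter in both comparisons, placed by its log2 difference for forskolin minus vehicle (horizontal) and high fat diet minus chow (vertical), from 1 array per group; dashed lines mark 2-fold. Red marks the 10 genes higher in both and blue the 14 genes higher with forskolin and lower on the high fat diet.

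Cultured adipocytes carried lower median levels of endothelial, mesothelial, fibroblast and macrophage markers than whole fat. Against the chow array, the vehicle array was at least 18.6-fold lower at the median of the endothelial markers, at least 7.86-fold for mesothelial and at least 2.80-fold for macrophage markers, since 3 members of each list were at the vehicle floor. It was 5.43-fold lower for fibroblast markers. It was at least 2.80-fold lower for smooth muscle, 1.69-fold for neutrophil and mast cell, 1.36-fold for red blood cell and 1.29-fold for B cell markers, each with 1 member at that floor. Skeletal muscle markers were 1.19-fold lower, also with 1 member at that floor. The T cell list was 1.07-fold lower, with 4 of 8 members lower. The epididymis list was 1.10-fold higher, with 3 of 6 lower and 1 at that floor. The adipocyte list was 1.18-fold lower, and housekeeping genes were 1.41-fold higher. Sample type and array batch cannot be told apart in this comparison.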

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

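No paired analysis was possible because each group holds 1 array. The cause of each move below was not tested, except that a looser or stricter threshold or filter by construction changes how many genes count.

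With a 1.5-fold threshold, 159 genes were higher and 43 lower with forskolin, and 2004 higher and 1037 lower with the high fat diet. The overlap then held 26 genes higher in both, 7 lower in both, 38 higher with forskolin and lower on the diet, and 11 the other way. With a 3-fold threshold the counts were 51 and 1 for forskolin and 564 and 141 for diet. Without the level filter they were 252 and 142 for forskolin, and 962 lower for diet; the overlap held 32 higher in both, 18 lower in both, 42 and 20. With the filter at the 75th percentile, 2 genes were lower with forskolin, and 665 higher and 211 lower on the diet. Quantile normalization gave 845 lower genes on the diet and 0 genes lower in both.

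With the median over probe sets, 0 genes were lower in both, and the log2 differences of Egln3 (0.672) and Rcan3 (0.060) with forskolin and of Sema3b (0.053) on the diet turned from lower to higher. No list lay below the random range with forskolin under that choice (0). With members passing the filter only, the count was also 0. The T cell and the neutrophil and mast cell lists then had 0 and 1 members, too few to be placed. That second count therefore says nothing about them. The median of the forskolin-higher genes on the diet was 0.019 with the median over probe sets and 0.019 with a 3-fold threshold, both chosen after the data were seen, against -0.004. Its alternatives ranged from -0.230 to 0.019, inside their random ranges except for the 59 genes passing the filter in both comparisons (-0.130). The remaining values lay within 1.5 times of the main count or within 0.58 on the log2 scale, except 13 values of named genes and 1 list median. Of those, Crem on the diet turned from 0.407 to -0.263 with the median over probe sets, and the inflammatory list moved from 0.869 to 1.744 with members passing the filter only. Low signal over background limits the thermogenic, T cell, mesothelial and epididymal lists with forskolin, where 0 members reach the level filter.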

Other observations

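All tests in this part, and the added interferon, lysosome and handling lists, were chosen after the results were seen; some members of the added lists had been looked at first. Ucp1 was also named for the diet after its values were seen.

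Interferon-stimulated and lysosomal genes were also higher at their medians in fat from the high fat diet. There, macrophage markers had a median of 6.55-fold higher (18 of 18 measured members at least 1.5-fold). The T cell, B cell and neutrophil and mast cell lists had medians of 3.60-fold, 3.10-fold and 5.34-fold higher. Only 3 of 6 measured T cell and 2 of 7 B cell members reached the level filter, and the neutrophil genes S100a8 and S100a9 were 2.35-fold and 1.3-fold higher. Of 25 measured interferon-stimulated genes 23 were at least 2-fold higher and none 2-fold lower, with a median of 6.06-fold (percentile 100 among level-matched random lists). Stat2, which carries the interferon signal, was 18.8-fold higher, Bst2, which tethers viruses to cells, 11.1-fold, and the GTPase genes Igtp and Iigp1 10.7-fold and 10.2-fold. After quantile normalization the median log2 difference was 2.45. With forskolin the same list had a median of -0.07, below its random range of -0.05 to 0.05 (percentile 0.3), and no member 2-fold apart. Of 22 lysosomal genes 15 were at least 2-fold higher on the high fat diet, with a median of 2.54-fold, including the protease genes Ctsk (9.11-fold) and Ctsz (5.82-fold) and the glycosidase genes Gusb (7.34-fold) and Gla (6.76-fold).

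Fos, Atf3, Egr1, Egr2, Jun and Junb were at least 2-fold higher both with forskolin and on the high fat diet. If the whole tissue showed a forskolin-like response, the 82 forskolin-higher genes should stand above random lists on the diet. Their median was -0.004, with a bootstrap interval over genes of -0.31 to 0.26 that reached the top of the random range of 0.26. A weaker response may therefore be present, and this cannot be told apart. Their forskolin median of 1.67 is high by selection, since they were chosen for a forskolin fold of at least 2, so it is no yardstick here. Leaving out those 6 genes, which was tried first, gave -0.08, and the 59 genes passing the level filter in both comparisons gave -0.13, below their random range. The list of early cAMP targets, written before the data were examined, had a diet median of 0.053, inside its random range (percentile 44.9). Of its 21 measured members, 4 were at least 2-fold higher, all of them among the 6 genes, and 2 were lower. Handling or heat stress at collection could also raise such genes, and a list of 17 stress genes had a median of 0.312 (percentile 72.7, interval -0.18 to 0.78), which left it open.

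Immune and mast cell markers were higher but endothelial, mesothelial and smooth muscle markers lower at their medians on the high fat diet. A lower share of adipocytes alone would raise the markers of all other cells alike. The 22 endothelial, mesothelial and smooth muscle genes had a median of -0.861 (interval over genes -1.11 to -0.73) and the 31 macrophage, B cell, neutrophil and mast cell genes 2.55 (1.70 to 2.91). These lists were grouped by direction after their values were seen, so the medians restate the pattern and are no separate test. The fibroblast and T cell lists, 1.37-fold and 3.60-fold higher at their medians, were in neither group. Between these single arrays, lower medians for non-adipocyte markers are not what a lower share of adipocytes alone would give. The prediction for a brighter high fat array was a closed gap after quantile normalization, but the gap was 3.562 (2.62 to 4.06). The medians became -1.167 and 2.395. Both groups moved down, so the gap could hardly have closed, and its staying open does not decide on brightness. A change in cell makeup with the diet may account for the pattern, as may a difference between the mice or dissections, which 1 array per group leaves untested. Whether RNA was pooled over mice is not given in the sources used here.

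Branched-chain amino acid breakdown genes were lower at their median on the high fat diet, with 5 of 15 at least 2-fold lower and 5 within 1.5-fold, and fewer adipocytes per unit of tissue RNA could be the cause. The 15 genes had a median of -0.76, and 11 adipocyte and lipid droplet genes with chow intensities under 5000 had -0.64, a gap of -0.124 with an interval over genes of -0.74 to 0.63. With chow intensities under 10000 the gap over 18 adipocyte genes was -0.50 (-0.89 to 0.11), and with no limit, over 23 genes of median -0.25, it was -0.51 (-0.91 to 0.11). These gaps are larger, but each interval holds 0, so a change in this pathway and a lower share of adipocyte RNA cannot be told apart.

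Ucp1 was at least 15.6-fold higher on the high fat diet, with chow at the floor. The thermogenic list of 10 genes had a median of -0.28, inside its random range, with 1 member at least 2-fold higher and 2 lower. The Ucp1 levels were below the level filter in both comparisons.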
